A study of Casuarina glauca with 15 samples.

How the data were processed

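RNA from roots and nodules of the tree Casuarina glauca was measured on 15 one-colour arrays, in 5 groups of 3 arrays, each array holding 14543 probes of 60 bases for the plant's assembled sequences. Of non-inoculated roots there were groups without nitrogen on day 0, without nitrogen on day 7 and with nitrogen on day 7. The other groups were inoculated roots without nitrogen on day 7 and nodules, also without nitrogen, on day 21 after inoculation with the bacterium Frankia. The labels do not say whether the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

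Scanner files gave the Cy3 intensity of each spot, which per the file headers was background-subtracted and detrended by Agilent Feature Extraction and not scaled between arrays. The submitters' processing notes name Agilent Feature Extraction 9.1, while the file headers give module version 9.5.1.1. The deposited value table holds a linear ratio for 12377 of the probes, with a lowest value of 0.01. Differences between arrays in that table followed the scanner intensities, with correlations across probes of 0.956 to 0.996 per array. Row medians lay within 0.1 of 1 for 93.7% of its probes, and column medians ran from 0.888 to 1.16, so each probe appears centred on its median. How the authors scaled the arrays in that table stays unknown, and it was used only as an alternative.

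The log2 of the processed signal was taken and each array's 75th percentile over the non-control probes was subtracted. The 536 control spots per array were left out, and spots with an outlier flag, at most 9 on an array, were set to missing. A probe was tested when it was well above background on all 3 arrays of at least 1 group, which kept 10659 probes. One linear model with a mean per group was fitted over the 15 arrays with limma 3.58.1 in R 4.3.3, with moderated variances and no trend. Benjamini-Hochberg adjustment was made over probes for each comparison, and a probe was called at an adjusted p under 0.05. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. A probe well above background in one group and on no array of the other has only a bound there. That bound is the bright group's mean over the dim group's mean of, per array, the lowest signal among probes well above background or the probe's own signal, whichever is higher, and is given as at least N-fold.

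Every probe carried the description Unknown, and no table pairing probes with genes was used here. Only 4 probe IDs hold a gene symbol. Of 32 gene lists fixed before the data were examined, 1 matched any probe: symbiosis signalling, with 2 probes. The list is too small for a set test, and the other 31 lists, among them other cell types and bacterial sequence, had no matched probe and gave no result. The rule for named probes was also fixed before the data were examined. Where probes have no gene names, it takes at most 2 IDs that rose and 2 that fell most among called probes whose groups do not overlap. It does not mention gene symbols held in probe IDs. Probes with such a symbol are given in every comparison as well, whatever their result. After the data were seen the rule for IDs was narrowed to probes well above background and not saturated on all 6 arrays compared, because values at the floor have no order. An ID that is itself a database accession is not printed.

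The test was checked on simulated data with the real probe means and spreads and 200 probes changed by known folds, in 10 simulations per comparison. With the same noise on every array, 4.88% of calls were false for inoculated against non-inoculated roots on day 7, and 86% of 4-fold changes and 47.8% of 2-fold changes were recovered there. Array 2 of the day 7 roots without nitrogen is much noisier than the others, with a noise SD of 1.102 log2 against 0.413 and 0.261 for the others of its group. With each array given its own noise, from differences between pairs of arrays, false calls were 7.36% for that comparison, 8.5% for day 7 against day 0, 4.16% for with against without nitrogen and 0.863% for nodules against day 0. A cruder noise estimate, the spread around the mean of 3 arrays, was tried first. It gave 33.8%, 31.5%, 25.2% and 0.872% for those 4 comparisons. The first 3, with medians of 68, 62 and 44 false calls, exceeded a limit of 40 set for the check, and the last had 1. For nodules against day 7 roots without nitrogen the cruder estimate gave 20.8%, with up to 49 false calls, against 2.59% with noise from pairs of arrays. The estimate was replaced after that result was seen, because the noisy array raises the estimate for its 2 partners. The simulations treat probes as independent, so shared shifts of an array are not covered.

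The number of arrays limits the precision. The arrays lay on 2 slides, of 8 and 7 arrays, each holding all 5 groups, and each slide was scanned as one batch. Alternatives were quantile scaling, median centring, normexp background correction with an offset of 50, the deposited ratios, other filters on dim probes, slide or replicate number as a block, a fit of only the groups compared, another variance model, Student's test per probe, and leaving out each array. Added after the data were seen were each slide alone and limma's array weights, leaving out arrays outside the groups compared, and for named probes also slide as a block, the fit of only the groups compared, the other variance model and Student's test.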

Results

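Transcript levels were measured in roots and nodules of Casuarina glauca, a tree that forms nitrogen-fixing nodules with the soil actinobacterium Frankia. Each of the 5 groups held 3 arrays. Between 59.1% and 74% of the 14543 probes were well above background per array, and the 75th percentile of the signal ran from 1738 to 4111 intensity units. Array 2 of the day 7 roots without nitrogen had the lowest share, and the lowest share among the other arrays was 65.5%. That array correlated with the others of its group at 0.947 to 0.95 across probes, while arrays 1 and 3 of that group reached 0.987. Levels below are log2 signals relative to the array's 75th percentile.

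The 4 probes with a gene symbol were CG-SymRK, named after the symbiosis receptor-like kinase, CgDMI3, named after the calcium- and calmodulin-dependent kinase of symbiotic signalling, CL747Contig1(CgFNR) and CL40Contig1(CgFdx), whose symbols are those of ferredoxin-NADP reductase and ferredoxin. All of them were well above background on the 15 arrays. The CG-SymRK probe, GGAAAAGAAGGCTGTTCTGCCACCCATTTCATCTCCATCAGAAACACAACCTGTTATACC, gave 3.14 ± 0.07 (SD, n = 3) in nodules. The CgDMI3 probe, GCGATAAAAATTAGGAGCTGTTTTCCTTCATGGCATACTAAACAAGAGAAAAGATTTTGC, gave -0.69 ± 0.2 (SD, n = 3) in day 0 roots. These 2 probes are the symbiosis signalling list, and their count past the threshold adjusted over the list alone equalled that over all probes in every comparison.

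**Figure D1:**
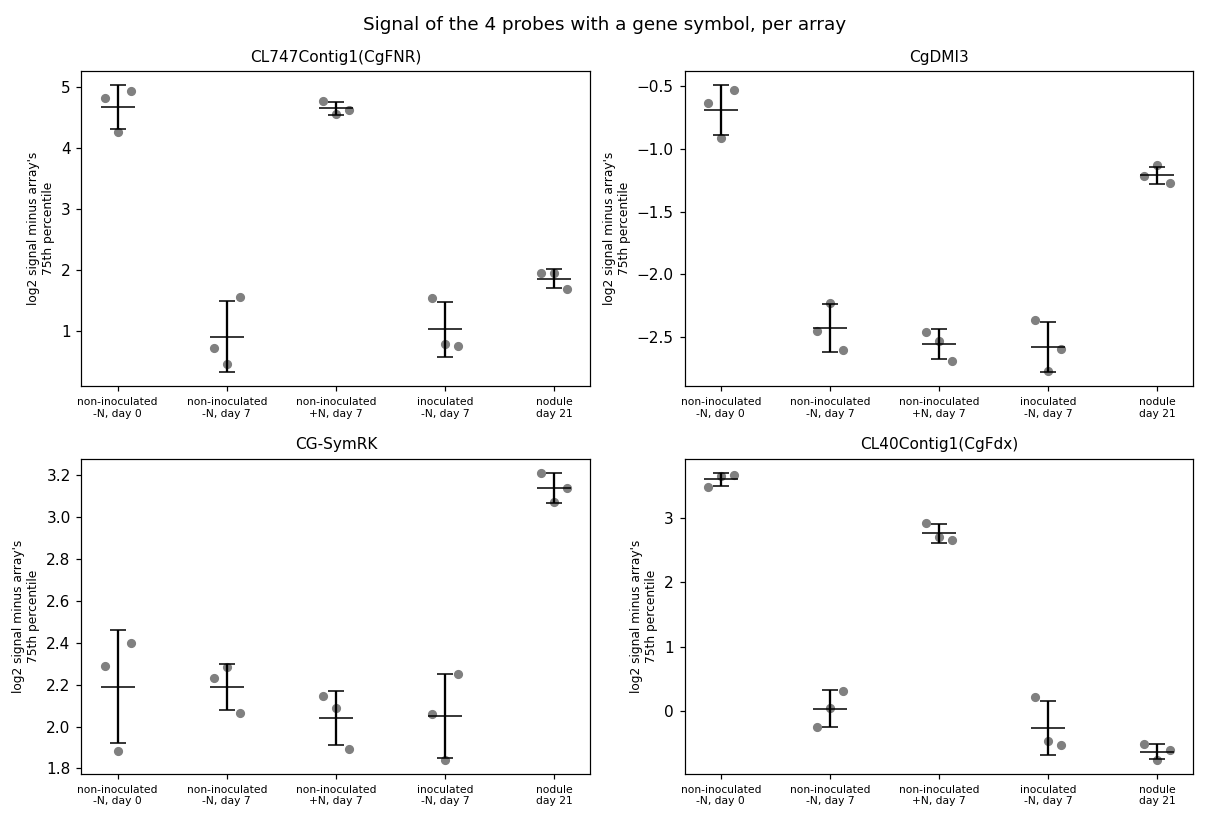
Log2 signal minus the array's 75th percentile (y axis) for the 4 probes with a gene symbol in the 5 groups (x axis). Grey points are arrays, and bars give the mean and SD of 3 arrays; CG-SymRK stood at 3.14 in nodules and between 2.04 and 2.19 in the root groups.

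The first comparison set nodules against roots on the day of inoculation, so organ, age and inoculation differed together. CG-SymRK was 1.93-fold higher in nodules, by 0.95 ± 0.16 log2 (SE, n = 3 per group, adjusted p = 0.00023). CL40Contig1(CgFdx) was 18.7-fold lower in nodules, at -0.63 ± 0.12 against 3.6 ± 0.1 (SD, n = 3, adjusted p = 1.2e-09). CL747Contig1(CgFNR) was 6.98-fold lower (adjusted p = 2.1e-06). CgDMI3 was 1.43-fold lower (adjusted p = 0.014), a call lost without array 3 of the day 0 roots, where the log2 difference was -0.43. Within slide 1 alone CG-SymRK differed by 0.92 log2 and was not called, and CgDMI3 was called within neither slide, at -0.58 and -0.48. Among unnamed probes, CGCL2388Contig1 was 3220-fold and CGCL139Contig1 2630-fold higher in nodules, or 755-fold and 556-fold with normexp, while CG-R02f_011_B02 was 225-fold and CG-R02f_048_H06 223-fold lower. In all, 5551 of 10659 probes differed, 2683 higher and 2868 lower in nodules, against 1616 and 3037 with normexp. The balance turned in the authors' ratios, to 2712 and 2391, and was near even when only the 6 arrays compared entered the fit, at 3369 and 3364, within slide 2, at 2653 and 2649, and without array 2 of the day 7 roots without nitrogen, at 3533 and 3513. A rise of at least 32-fold was fitted for 373, of which 267 were well above background on no day 0 array, and 189 of these reached 32-fold at their lower bound. A further measure covers 464 probes well above background on every nodule array and on no day 0 array, which were a median of at least 16.2-fold higher. With slide as a block 5550 probes were called, and 1976 and 5302 within slides 1 and 2.

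Nodules were also compared with day 7 roots kept without nitrogen. CG-SymRK was again 1.93-fold higher (adjusted p = 0.00024). CgDMI3 was 2.33-fold higher in nodules, at -1.21 ± 0.07 against -2.43 ± 0.19 (SD, n = 3, adjusted p = 1.9e-05). CL747Contig1(CgFNR) was 1.93-fold higher and CL40Contig1(CgFdx) 1.59-fold lower (adjusted p = 0.014 for each). Against day 0 roots CgDMI3 and CL747Contig1(CgFNR) had been lower in nodules, so their direction depended on the control. The call for CL40Contig1(CgFdx) was lost without array 2 of the nodules, at -0.6 log2, or array 3 of the day 7 roots, at -0.53, and that for CL747Contig1(CgFNR) was lost with normexp, at 0.9, and when only the 6 arrays compared entered the fit. The authors' ratios gave -0.28 for CL40Contig1(CgFdx), which was not called. Within slide 1 alone none of the 4 was called, at 0.95 for CG-SymRK, 1.12 for CgDMI3, 1.36 for CL747Contig1(CgFNR) and -0.42 for CL40Contig1(CgFdx), and CL747Contig1(CgFNR) was not called within slide 2, at 0.26. CGCL244Contig1 was 915-fold higher in nodules, but 537-fold without array 1 of the day 7 roots, 580-fold with normexp, and 1400-fold and 402-fold within slides 1 and 2. CGCL1268Contig1 and CG-R02f_029_N05 were 163-fold and 160-fold lower, or 104-fold and 61-fold with normexp and 91.1-fold and 98.4-fold in the authors' ratios, and the second was 288-fold lower within slide 1. There were 2700 probes higher and 2928 lower in nodules, against 3819 and 1936 in the authors' ratios and 2628 and 5107 with no filter on dim probes. With slide as a block 5470 probes were called, and 2370 and 4336 within slides 1 and 2.

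The third comparison set inoculated against non-inoculated roots on day 7. No difference of the 4 named genes passed the test. CG-SymRK stood at 2.05 ± 0.2 in inoculated and 2.19 ± 0.11 in non-inoculated roots (SD, n = 3, adjusted p = 0.59), and CgDMI3 at -2.58 ± 0.2 and -2.43 ± 0.19 (adjusted p = 0.56). CG-N02f_035_A14 was 142-fold higher in inoculated roots, at 5.62 ± 0.14 against -1.53 ± 2.07 (SD, n = 3, adjusted p = 0.00038). CGCL2239Contig1 was 82.1-fold higher (adjusted p = 0.0022). Both probes have 55% GC and also stood high on the nodule arrays, at 4.51 to 5.24 and 2.86 to 3.3. Whether the signal of such GC-rich probes comes from the plant or the bacterium was not tested. CG-N02f_035_A14 stood at 0.86 on array 3 of the non-inoculated roots and at -2.6 and -2.84 on the other 2, and was 89.9-fold and 324-fold higher without arrays 2 and 3 of that group and 307-fold and 30.3-fold within slides 1 and 2. CGCL2239Contig1 was 36.3-fold and 165-fold higher without arrays 1 and 3 of that group and 18.3-fold within slide 2. CG-N02f_012_E07 and CG-N02f_036_F13 were 5.12-fold and 4.6-fold lower (adjusted p = 0.0023 and 0.00032). Only 184 probes were called, 119 higher and 65 lower, and the count depended on the fit. It was 1 when only the 6 arrays compared entered the fit, which called none of the named probes, 98, 82 and 122 without arrays 1, 2 and 3 of the inoculated roots, 107, 111 and 113 without nodule arrays 1, 2 and 3, 120 and 109 without arrays 1 and 2 of the roots with nitrogen, 153 with slide as a block, and 3 and 32 within slides 1 and 2. Leaving out array 2 of the non-inoculated roots gave 211 calls, of which 123 were among the 184. Neither named fall was called within slides 1 and 2, at -2.8 and -1.46 log2 for CG-N02f_012_E07 and -2.42 and -1.76 for CG-N02f_036_F13, against -2.36 and -2.2 over all arrays. CG-N02f_036_F13 was not called with normexp either, at -1.64, nor was CGCL2239Contig1 within slide 1, at 7.44.

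**Figure D2:**
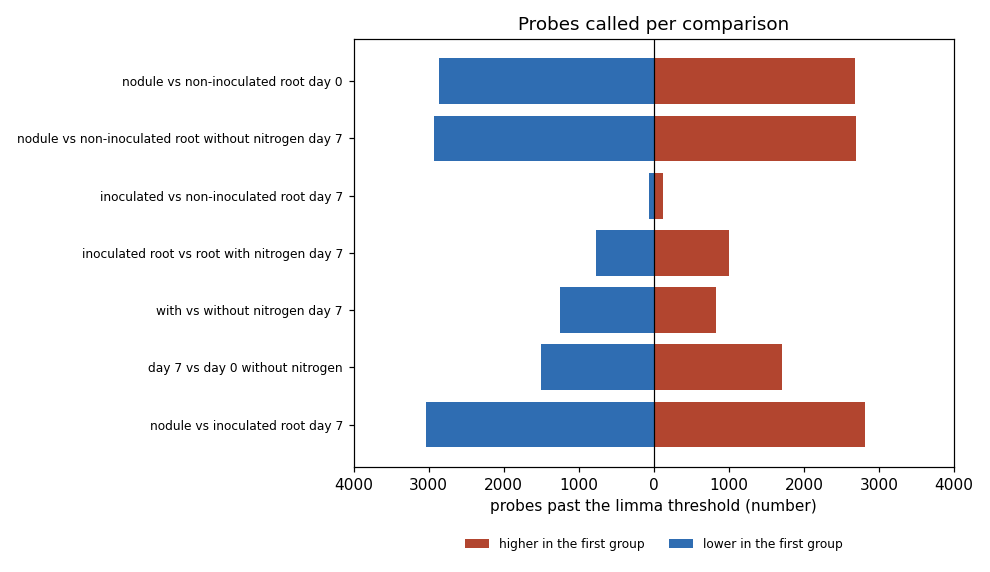
Number of probes past the limma threshold (x axis) in 7 comparisons (y axis), to the right where higher and to the left where lower in the group named first. The comparison of inoculated with non-inoculated roots on day 7 had 119 probes higher and 65 lower, the fewest of the 7.

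Inoculated roots without nitrogen were next set against non-inoculated roots with nitrogen on day 7. CL747Contig1(CgFNR) was 12.3-fold lower in the inoculated roots, at 1.03 ± 0.45 against 4.65 ± 0.11 (SD, n = 3, adjusted p = 3.6e-06), and CL40Contig1(CgFdx) was 8.09-fold lower (adjusted p = 9.5e-07). CG-SymRK and CgDMI3 did not pass the test, with log2 differences of 0.01 ± 0.16 and -0.01 ± 0.16 (SE). CG-N02f_035_A14 was 814-fold and CGCL1784Contig1 122-fold higher, both probes of 55% GC, and CG-R02f_041_G12 and CGCL360Contig1 were 28-fold and 23.6-fold lower. Within slide 2 the first was 1480-fold higher and the third 43.7-fold lower, and the third was 16.9-fold lower with normexp. In all 1002 probes were higher and 764 lower, a balance that turned with median centring, to 677 and 792, quantile scaling, to 856 and 974, normexp, to 427 and 438, and normexp with quantile scaling, to 927 and 1067. With slide as a block 1745 probes were called, 135 and 210 within slides 1 and 2, 994 and 1157 without arrays 1 and 2 of the inoculated roots, 1080 and 1132 without arrays 1 and 3 of the roots with nitrogen, and 3502 without array 2 of the roots without nitrogen, which enters only the shared spread.

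Nitrogen was compared in non-inoculated roots on day 7. CL747Contig1(CgFNR) was 13.3-fold higher with nitrogen, at 4.65 ± 0.11 against 0.91 ± 0.58 (SD, n = 3, adjusted p = 2.4e-06). CL40Contig1(CgFdx) was 6.59-fold higher with nitrogen (adjusted p = 2.1e-06). CG-SymRK and CgDMI3 did not pass the test, with adjusted p = 0.54 and 0.58. CG-R02f_041_G12 was 34-fold and CG-R02f_042_G13 32.9-fold higher, the latter at 1.54 ± 2.18 against -3.5 ± 1.86 (SD, n = 3, adjusted p = 0.035). That call was lost without arrays 1 or 2 of the roots with nitrogen, at 5.61 and 3.78 log2, without arrays 1 or 3 of those without it, at 4.22 and 4.85, with normexp, at 4.44, within slides 1 and 2, at 5.53 and 4.06, and when only the 6 arrays compared entered the fit. The rise was 52.7-fold without array 3 of the roots with nitrogen, 66.3-fold without array 2 of those without it and 82.1-fold with array weights. With normexp CG-R02f_041_G12 was 19.6-fold higher. CG-J07f_002_M11 and CG-N02f_027_O13 were 18.1-fold and 17.5-fold lower with nitrogen, the first 10.9-fold within slide 2 and the second 8.63-fold with normexp. Within slide 2 CL747Contig1(CgFNR) was 8.34-fold higher. There were 832 probes higher and 1252 lower with nitrogen, against 1013 and 688 in the authors' ratios, 834 and 2857 with no filter on dim probes, 486 and 479 with normexp and 344 and 337 when only the 6 arrays compared entered the fit. With slide as a block 2063 were called, 163 and 331 within slides 1 and 2, 681 when only the 6 arrays compared entered the fit, and 1203, 1380 and 1369 without arrays 1, 2 and 3 of the roots with nitrogen.

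Day 7 and day 0 were compared in non-inoculated roots without nitrogen. CL747Contig1(CgFNR) was 13.5-fold lower on day 7 (adjusted p = 2.1e-06), CL40Contig1(CgFdx) 11.8-fold lower (adjusted p = 2.8e-07) and CgDMI3 3.33-fold lower (adjusted p = 7.2e-06). CG-SymRK was at 2.19 in both groups (adjusted p = 0.99). Within slide 1 alone the first 3 were not called, at -4.22, -3.58 and -1.71 log2, and within slide 2 CL747Contig1(CgFNR) was 8.22-fold lower. CG-R02f_010_I23 and CGCL535Contig1 were 15.8-fold and 14.5-fold higher on day 7, the second 5.62-fold with normexp, and CGCL360Contig1 and CG-R02f_040_L14 were 48.6-fold and 33.2-fold lower. There were 1704 probes higher and 1509 lower, against 719 and 2167 in the authors' ratios, 738 and 1135 with normexp and 469 and 571 when only the 6 arrays compared entered the fit. With slide as a block 3126 were called, 8 and 1369 within slides 1 and 2, 1040 when only the 6 arrays compared entered the fit, and 4917 without array 2 of the day 7 roots.

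Nodules were finally compared with inoculated roots of day 7. CgDMI3 was 2.59-fold higher in nodules (adjusted p = 5.9e-06) and CG-SymRK 2.13-fold higher (adjusted p = 6.7e-05), though CG-SymRK was not called within slide 2 alone, at 0.86 log2. CL747Contig1(CgFNR) was 1.79-fold higher (adjusted p = 0.025), a call lost without array 1 or 2 of the nodules, at 0.79 log2 each, and without array 2 or 3 of the inoculated roots, at 0.72 and 0.7. It was not called with normexp either, at 0.75, or at 0.67 with quantile scaling added, nor within slides 1 and 2, at 0.79 and 1.07. CL40Contig1(CgFdx) did not pass the test, at -0.63 ± 0.12 against -0.26 ± 0.42 (SD, n = 3, adjusted p = 0.14). CGCL167Contig1 was 2110-fold and CG-N02f_029_E15 2080-fold higher in nodules, and CG-R02f_043_L05 and CGCL2131Contig1 were 441-fold and 315-fold lower. With normexp these folds were 1210, 662, 176 and 174, and CGCL2131Contig1 was 180-fold lower within slide 2. There were 2820 probes higher and 3042 lower in nodules, a balance that turned in the authors' ratios, to 2829 and 2637, and with median centring, to 2814 and 2768. With slide as a block 5801 were called, and 2639 and 4448 within slides 1 and 2.

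The difference between the nodule effect against day 0 and the inoculation effect on day 7 was tested in the same fit. CG-SymRK differed by 1.09 ± 0.23 log2 (SE, adjusted p = 0.0015), with effects of 0.95 and -0.14. CL40Contig1(CgFdx) differed by -3.93 ± 0.29 (adjusted p = 1.3e-07) and CL747Contig1(CgFNR) by -2.92 ± 0.41 (adjusted p = 5.7e-05). Both depended on the day 0 control. In non-inoculated roots without nitrogen they changed by -3.56 and -3.75 log2 from day 0 to day 7. Against those day 7 roots nodules differed by only -0.67 and 0.95. Over all probes 4865 differed, 2347 with the nodule effect above the inoculation effect and 2518 with it below. The balance was 2482 and 2431 with normexp and quantile scaling, and 4853 probes differed when slide was a block. Each difference also holds the change in non-inoculated roots from day 0 to day 7, which alone was called for 3213 probes. The nodule and the inoculation comparison use different arrays but share the same estimate of spread per probe. Their lists are therefore not independent, and the p-values below only describe. In both, 36 probes were called in the same direction, 18 higher and 18 lower, where independent lists would share 30 and 17.5. Another 82 probes were lower in nodules and higher after inoculation, where independent lists would share 32, and 27 went the other way against 16.4 (Fisher's exact test across probes, p = 9.1e-22 and 0.0038). Without array 2 of the non-inoculated day 7 roots these were 99 against 50.8 and 24 against 18.9 (Fisher's exact test, p = 1.4e-15 and 0.16), so the second excess no longer passed. The same-direction count was 36 with slide as a block and 3 and 5 within slides 1 and 2, and it was 22 without array 2 of the inoculated roots.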

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

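The tests of exchanged arrays, arrays with no common number, root age, labelling strength, slide, GC content and signal level, and that of the opposed effects without the noisy array, were chosen after the results were seen, as was the limit to measured probes in the test of probes at least 32-fold higher in nodules. The nodule effect and the day 7 inoculation effect differed for 4865 probes by the test of the difference. Among the named probes it was -2.92 log2 for CL747Contig1(CgFNR), 1.09 for CG-SymRK and -3.93 for CL40Contig1(CgFdx). The nodule effect has day 0 roots as control and the inoculation effect day 7 roots. Each difference thus holds the probe's change in non-inoculated roots from day 0 to day 7. For CL747Contig1(CgFNR) and CL40Contig1(CgFdx) that change was -3.75 and -3.56. Unnamed probes past the test of the difference were CGCL2388Contig1 at 15.3, CGCL139Contig1 at 14.54, CG-R02f_011_B02 at -8.8, CG-R02f_048_H06 at -8.14, CG-N02f_012_E07 at 4.45 and CG-N02f_036_F13 at 4.45. The first 2 of these were each well above background on only 1 of 3 inoculated arrays, and CGCL139Contig1 on 2 of 3 non-inoculated ones, so their inoculation effects of -3.64 and -3.18, and with them the size of these differences, rest on values near background.

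For the comparisons of 3 with 3 arrays, 10 splits are too few for a share under 0.05. In each, 1 split, the real one, gave as many calls. The real count and the highest other were 5551 and 0 for nodules against day 0, 5628 and 1 for nodules against day 7 roots without nitrogen, 184 and 5 for inoculation, 1766 and 1 for inoculated roots against roots with nitrogen, 2084 and 1 for nitrogen, 3213 and 2 for day 7 against day 0, and 5862 and 0 for nodules against inoculated roots. For the difference of effects, 1 of 100 splits gave as many calls, and the highest other split, which mixed the day 7 groups, gave 4822. Chance can thus be excluded only for the grouping of all these arrays together, not for a difference between the effects. For neither part alone can it be read from these splits: 12 of the 100 kept nodule and day 0 arrays apart, the other 11 of them gave 4045 to 4822 calls, and the remaining 88 gave at most 1. For the probes called in the same direction by both, 2 of 100 splits, both among those 12, gave 36 or more. The other one, with 109, exchanged the 2 day 7 groups.

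On probes that differed between inoculated roots and roots with nitrogen, day 0 roots mostly lay towards the roots with nitrogen, relative to day 7 roots without nitrogen. Across all probes, arrays of day 0 roots correlated with those of roots with nitrogen at 0.966 to 0.977, a mean of 0.973. With inoculated roots they correlated at 0.959 to 0.968, a mean of 0.964. With day 7 roots without nitrogen, which include the noisy array, it was 0.936 to 0.971, a mean of 0.959. Over the whole profile day 0 roots thus also correlated best with roots with nitrogen, by small margins and with overlapping ranges. Arrays of day 7 roots without nitrogen correlated with those of roots with nitrogen at 0.931 to 0.976. Of 970 probes that differed at least 2-fold between inoculated roots and roots with nitrogen, 733 (75.6%) were displaced the same way between the day 0 and day 7 roots without nitrogen, which are other arrays. The share was 73% or more under 5 other scalings and 72.2% without the noisy array, which argues against both as the cause, and 0 arrays of the 2 groups correlated best with the other group. Same-numbered arrays of day 0 roots and roots with nitrogen deviated together, with correlations of 0.222, 0.171 and 0.133, but with arrays of no common number the share was 71.7% to 78.9%, and 75.9% with a replicate block, which argues against this as the whole cause. Root age stays open, since there were 0 arrays of roots with nitrogen on day 0, and a hypothesis is that day 0 roots may still have held part of their earlier nitrogen state.

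Array 2 of the day 7 roots without nitrogen stood apart. Probes with stop codons in all 3 frames, a sign of untranslated sequence, lay 0.5 log2 higher than other probes there, relative to the other arrays of its group, and at most 0.09 higher on any other array. This is consistent with RNA lost away from the 3' end or in GC-rich probes, which the test does not separate. Arrays as dim correlated within their groups at 0.985 or more, and the mean correlation of its deviations with other groups' arrays on its slide was 0.039, which argues against weak labelling and the slide. No biological explanation was tested.

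Across probes, which are not independent replicates, the nodule and inoculation effects were opposed, with a correlation of -0.3, which fell in size to -0.17 across probes well above background on all arrays. Across tested probes it was -0.29 without the noisy array and -0.28 with trends in GC content and signal removed, which argues against these as the whole cause. A small share of nodule RNA in the non-inoculated day 7 samples would hardly lower probes that are lower in nodules, and among these the correlation was -0.15. That value was not taken without the noisy array or over measured probes alone, so it does not decide whether nodule RNA was present. For the 373 probes with a fitted rise of at least 32-fold in nodules that question also stays open. Of these, 85.5% were higher in non-inoculated roots, or 80.7% without the noisy array. Most lay near background, and among the 40 measured on all 6 arrays the share was 72.5%, or 57.5% without the noisy array. On arrays 1, 2 and 3 of the non-inoculated roots 65, 56 and 108 of the 373 were well above background. On those of the inoculated roots 59, 98 and 81 were. The shares were not taken without array 3 of the non-inoculated roots. A biological opposition is a hypothesis only.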

How the results depend on the processing

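Total calls for the 3 comparisons of nodules with roots stayed within 1.5 times under every alternative chosen before the data were examined, while the day 7 counts did not. Calls of at least 2-fold, 3633, 3762 and 3898 for nodules against day 0, day 7 and inoculated roots, fell to 2378, 2501 and 2562 over probes well above background on all arrays, and the second was 5983 with no filter. Each slide alone and the array weights were chosen after seeing the data, and a group then left with 1 array is assumed to vary like the others. The cause of a change was not tested, except that a slide alone has fewer arrays. Leaving out any 1 of the 15 arrays, with arrays outside the groups compared added after seeing the data, gave 4876 to 7046 calls for nodules against day 0, 4886 to 6669 against day 7 roots without nitrogen and 5201 to 7247 against inoculated roots, 82 to 224 for inoculation, 994 to 3502 for inoculated roots against roots with nitrogen, 1203 to 2562 for nitrogen, 2427 to 4917 for day 7 against day 0, 4352 to 6088 for the difference of effects and 22 to 53 for the probes called in the same direction by both. Slide 1 alone gave 1976, 2370, 3, 135, 163, 8, 2639, 1657 and 3 calls for nodules against day 0, nodules against day 7, inoculation, inoculated against nitrogen, nitrogen, day 7 against day 0, nodules against inoculated, the difference and the shared calls. Slide 2 alone gave 32 for inoculation, 210 for inoculated against nitrogen, 331 for nitrogen, 1369 for day 7 against day 0, 3037 for the difference and 5 shared. Array weights gave 945, 4395, 3748, 4966 and 190 for inoculation, inoculated against nitrogen, nitrogen, day 7 against day 0 and shared. Normexp with the 75th percentile gave 63, 865, 965, 1873 and 16 for the same results. Fitting only the groups compared gave 1, 2877, 681 and 1040 for the first 4, and Student's test per probe gave 1 for inoculation, 355 for nitrogen and 669 for day 7 against day 0. Normexp with quantile scaling gave 346 for inoculation and 73 shared, the authors' ratios 298 for inoculation, no filter 95 for inoculation and 3691 for nitrogen, and only probes well above background on all arrays 22 shared. Higher against lower calls, 119 and 65 for inoculation, became 128 and 128 with quantile scaling, 177 and 169 with normexp and quantile scaling, 263 and 35 in the authors' ratios and 482 and 463 with array weights. With normexp, 2347 and 2518 for the difference became 1273 and 2086. Normexp shifted the median of all probes by -0.36 log2 for nodules against day 0, and the authors' ratios by 0.38 for nodules against day 7. The replicate numbers did not pair the arrays of any groups compared: at most 2 of the 3 same-numbered pairs had deviations correlated over 0.1. Day 0 roots and roots with nitrogen, which no test set against each other, had all 3 over it. With a replicate block 5479, 5577, 131, 1657, 1856, 3099, 5819, 4804 and 31 calls were made, in the order given for slide 1. Of the values for single named probes, 1618 kept their side of the threshold and 55 lost a call. No probe called over all arrays turned direction, while 24 of 300 values of probes not called had the other sign. Of the 55, 6 were lost when only the groups compared entered the fit and 8 with Student's test, both added for these probes after seeing the data. Student's test called none of the unnamed probes given for inoculation, nor CG-R02f_042_G13 for nitrogen, CL747Contig1(CgFNR) for nodules against day 7 and inoculated roots or CL40Contig1(CgFdx) for nodules against day 7. Normexp with quantile scaling lowered 19 folds of called probes picked by the rule by over 1.5 times and raised 0, a direction that the offset sets in advance for dim probes. Set tests of gene lists were not run, as no list had enough members. Background limits what can be measured: 2209 probes were well above background on none of the 15 arrays.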

Other observations

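The tests in this part were chosen after the results were seen. On the nodule arrays, 292 probes were well above background on 3 of 3 arrays and on 0 of 12 root arrays, a median of at least 16-fold higher. In the other direction, 72 probes were well above background on 12 of 12 root arrays and on 0 of 3 nodule arrays, a median of at least 21.7-fold higher in roots. Only 12 probes were well above background on all nodule arrays and at least 2 inoculated arrays and on 0 of 9 non-inoculated arrays.

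Probe IDs fell into series that differed in nodules. Of the tested CG-N probes, 24.5% were at least 2-fold higher and 8.42% lower in nodules than in day 0 roots, against 7.58% and 28.1% of the CG-R probes. Of the nodule-only probes 184 were CG-N and 12 CG-R, an odds ratio of 14.7 by Fisher's exact test across probes. A hypothesis is that CG-N sequences may come from nodule libraries, which the labels do not say.

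Of 1558 probes called both for nodules against day 0 and for nitrogen on day 7, comparisons that use different arrays, 1138 (73%) went in opposite directions. The share was 69.1% without the noisy array. With day 0 and with-nitrogen arrays of no common number, which matters since same-numbered arrays of these groups deviated together, it was 73.3% to 74.9%. With inoculated roots in place of day 0 roots it was 60.2%, or 51.4% without the noisy array. The opposition may thus rest on day 0 roots lying towards the roots with nitrogen. That position was seen on probes picked where Frankia and nitrogen differed together, and was not examined on probes called for nitrogen alone. A response shared with opposite sign stays open.

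Probes of at least 50% GC made up 14 of the 119 probes higher in inoculated roots on day 7 and 299 of the 10659 tested. The 14 include CG-N02f_035_A14 and CGCL2239Contig1, the largest rises named for inoculation. Of those 14, 9 (64.3%) were also higher in nodules, against 9 of the other 105 (8.57%, Fisher's exact test across probes, p = 6.8e-06). Of the 18 probes higher in both comparisons, 9 were thus GC-rich. Of all 299 GC-rich probes, 82 were higher and 90 lower in nodules than in day 0 roots, so GC-rich probes as a whole were not raised there. The median of those 9 probes was 3.8 to 4.09 log2 in inoculated roots and 2.86 to 3.49 in nodules. It was -2.36 or lower on the non-inoculated arrays except array 3 of the day 7 roots without nitrogen, at 0.6. All GC-rich probes together moved by a median of 0.22 log2 on day 7, against 0.01 for all tested probes. This argues against a large general trend with GC content but not against a small one. On array 2 of the non-inoculated day 7 roots, low-GC probes lay 0.73 log2 above probes of middle GC content, relative to its group. The GC-rich share of the 119 probes was not counted without that array. RNA of the bacterium, whose genome is rich in GC, is a candidate explanation, but the origin of these probes was not tested and a plant response stays open.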
